A study of Rubus occidentalis with 12 samples.

How the data were processed

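Genomic DNA of black raspberry (Rubus occidentalis), from an advanced breeding selection grown in the field, was examined by bisulfite sequencing in leaf and in fruit of 5 ripening stages, per the labels. Bisulfite converts unmethylated cytosine to uracil and leaves 5-methylcytosine in place, so the share of unconverted cytosines in the reads gives the methylation level. Cytosines are read in 3 contexts, CG, CHG and CHH, where H stands for A, C or T. Per the labels' protocols, DNA was isolated with CTAB and libraries were made with the ACCEL-NGS Methyl-Seq kit. That kit attaches adapters after conversion and adds a short synthetic tail to fragment ends, and bases of that tail left in reads would enter as false calls. Read trimming, the aligner, the caller, the genome build and any measured conversion rate are not given in the sources used here.

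The labels name 12 samples, 2 biological replicates in each of 6 groups. Files belong to the first replicate of each group only, 3 per group, 1 for each context. Whether the values come from that replicate alone or from both replicates pooled is not stated. Each group therefore gave 1 data set and no spread between replicates. The deposited values are fractions between 0 and 1, 1 per window of 50 bp, on a grid of 5816411 windows over 7 chromosomes named Ro01 to Ro07 that was the same in all 18 files. They are given here as percent. The files hold no counts of calls, so the depth behind each value is unknown, no confidence interval or detection limit can be given, and a window with few reads counts as much as a window with many. Positions are 1-based, as in the files, on a build not given in the sources used here.

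The planned test, Fisher's exact test on methylated and unmethylated calls, needs counts and was replaced by the form fixed in advance for fractions: the level is the unweighted mean of window values, and windows are listed by the size of their difference with no p-value. The same lack of counts ruled out minimum coverage, weighting and thinning. No genome or annotation was used here, so gene features, the gene lists by product keyword, the organelle share and gene names for regions were not analysed. The genome is described by 50-bp windows, by regions and by bins of 100 kb instead.

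Values were missing in a fixed order. With the 18 columns ordered from leaf CG, leaf CHG and leaf CHH through stage 1 to stage 5 CHH, no window (0 of 5816411) had a value after a missing one. The number of values per window peaked at 6 (964473 windows), 12 (1946310 windows) and 18 (2471150 windows). In windows with 12 values, the 6 columns at odd positions had a mean correlation over windows of 0.943, against 0.649 for columns of one named context. Cells without a value thus appear to have been dropped and the later values moved left, which puts values under another context or data set than the file says. The levels, differences, windows and regions reported below therefore use only the 2471150 windows with all 18 values, 42.5% of the grid, called complete windows. This choice was made after the data were seen. Windows that lack CG or CHG cytosines are left out by it. For CHH, values could also be moved back to their data set in windows with 12 values (even positions) and with 6 values (all positions), which gave 5381933 windows for an alternative that rests on the assumed shift.

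The 10 comparisons, given as first to second data set, were fixed before the data were examined: leaf to each of the 5 stages, each stage to the next, and stage 1 to stage 5. Leaf to stage 1 and stage 1 to stage 5 were the main ones. A window was called when its level differed by at least 30 percentage points in CG or CHG, or 15 points in CHH. Called windows of one direction whose ends lay within 200 bp were merged, and a region needed at least 2 called windows. In the main comparisons, the number of regions was set beside the mean of 10 random placements of the calls within 20 strata of the window's mean level over the 6 data sets. Overlaps of calls in 2 contexts were set beside independent calls within strata of both levels. Both expectations were chosen after the results were seen, and they do not account for depth or for a level that the change itself moved. Levels of a region are means over all its complete windows, with the SD over windows. The spread of a genome-wide level is the SD between the 7 chromosomes, which shows how even a value is along the genome. Chromosomes of one library are not replicates. Bins of 100 kb with at least 50 complete windows (2910 bins) were divided into 4 equal groups by mean CG level over the 6 data sets.

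Regions are named by a rule fixed before the data were examined. For each main comparison, context and direction, the rule takes the 4 regions with the most called windows, ties going to the larger difference and then to position. For each other comparison it takes the first region per context and direction. Of the latter, the text names those of CG and, between successive stages, those of CHH. Called windows of the main comparisons were followed through all 6 data sets. The overlap of calls against the shared leaf data set was set beside a simulation without effects, in which differences between stages 4 and 5, shuffled within 20 strata of level, stood for noise.

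The window and region steps were tested on 200000 complete windows with simulated CG losses of 60 points between stage 1 and stage 5. All lowered windows (100%) were recovered, and 0 unchanged windows were called under normal noise with an SD of 5 points, which lacks the wide tails that windows with few reads can give. CHH values moved left by construction were moved back without error in 100% of cases. Alternatives were lower and higher difference thresholds, merge distances of 50 and 500 bp and at least 4 windows per region, all planned. Added after seeing the data were all windows as deposited, CHH moved back, all contexts corrected for the level in unmethylated windows, and region levels over called windows alone. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, pyarrow 21.0.0 and matplotlib 3.10.9.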

Results

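DNA methylation was measured in leaf and in fruit at 5 ripening stages of black raspberry to follow how methylation changes between tissues and as fruit ripens. Each of the 6 groups has 2 labelled biological replicates and 1 data set, so no difference below has a replicate check, and no p-value is given. Depth is unknown. Errors are the SD between 7 chromosomes for genome-wide levels and the SD over windows for regions. Both describe evenness within a data set, not error between plants.

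**Figure D1:**
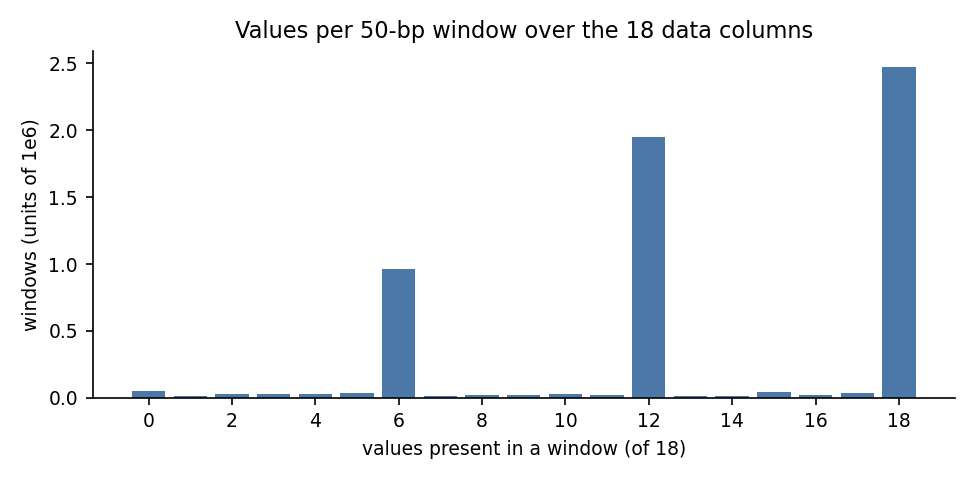
Number of 50-bp windows (vertical axis, in units of 1e6) by how many of the 18 columns hold a value (horizontal axis). Bars peak at 6, 12 and 18 values, and the results use the 2471150 windows with 18.

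CHG and CHH methylation were lowest in leaf, while CG methylation was close in all 6 data sets. Mean CG was 53.8% ± 1.68 in leaf, 54.7% ± 1.80 in stage 1, 54.7% ± 1.80 in stage 2, 53.2% ± 1.83 in stage 3, 53.0% ± 1.83 in stage 4 and 52.5% ± 1.83 in stage 5. Mean CHG was 22.5% ± 1.16 in leaf, 30.05% ± 1.38 in stage 1, 31.4% ± 1.38 in stage 2, 28.3% ± 1.33 in stage 3, 27.4% ± 1.30 in stage 4 and 26.9% ± 1.27 in stage 5. Mean CHH was 4.33% ± 0.1504 in leaf, 7.35% ± 0.302 in stage 1, 12.2% ± 0.410 in stage 2, 8.83% ± 0.368 in stage 3, 7.98% ± 0.349 in stage 4 and 8.23% ± 0.356 in stage 5. As a background measure, CHH in the 903572 windows with mean CG and CHG below 5% was 0.712% in leaf, 0.516% in stage 1, 2.49% in stage 2, 0.561% in stage 3, 0.424% in stage 4 and 0.695% in stage 5. In stage 2 those windows also read 2.35% in CG and 2.34% in CHG. With all windows taken as deposited, in which values appear displaced, the CG level was 30.3% in stage 1 and 52.1% in stage 5.

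**Figure D2:**
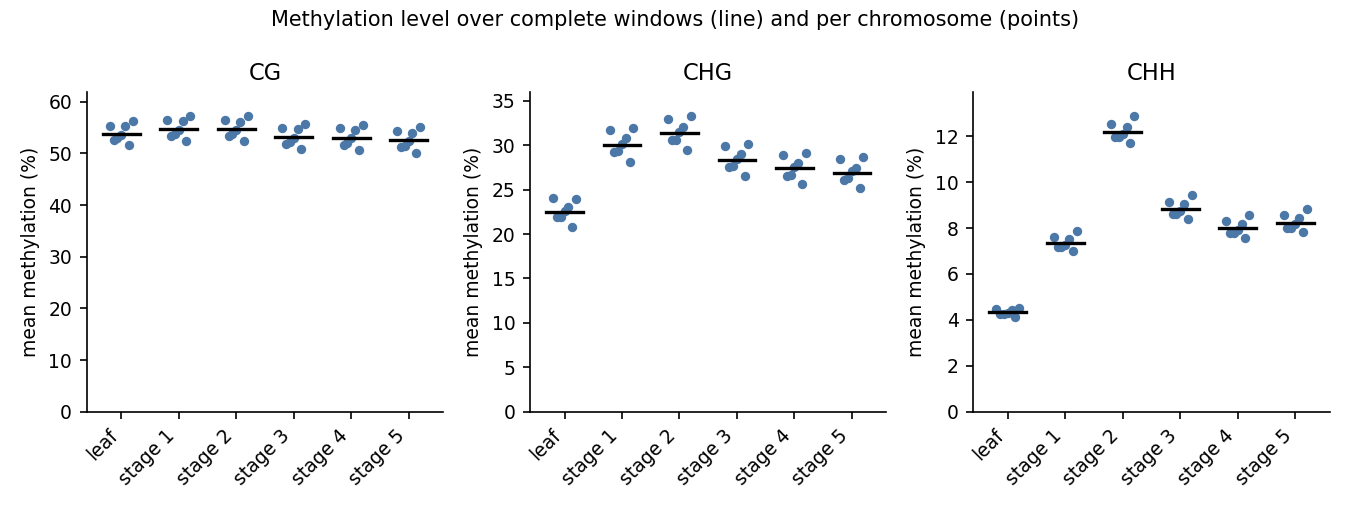
Mean methylation (percent, vertical axis) of the 6 data sets in CG, CHG and CHH over complete windows, with lines for the mean over all windows and points for the 7 chromosomes. CHG and CHH are lowest in leaf (22.5% and 4.33%), and CHH is highest in stage 2 (12.2%), whose background is also raised.

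The comparison of leaf with stage 1 fruit addresses differences between tissues. Fruit had more non-CG methylation: CHG was 7.56 percentage points higher (SD 0.254) and CHH 3.02 points higher (SD 0.157) in stage 1, each on 7 of 7 chromosomes. CG was 0.928 points higher (SD 0.127). With all windows as deposited, in which values appear displaced, the CG and CHH differences were -6.79 and -7.79 points, opposite in sign. The CHG difference was then 14.4 points. In CHG, 250558 windows were called higher and 25296 lower in stage 1. In CHH, 146763 were higher and 16727 lower. In CG, 26973 were higher and 17699 lower. Stages 4 and 5 were the pair of fruit data sets closest in mean CHG and CHH level. They differed by 41613 CHG windows higher and 46595 lower, and by 44023 CHH windows higher and 43021 lower. The CHG and CHH windows lower in stage 1 than in leaf were thus fewer than those between stages 4 and 5, and those higher were 6.02 and 3.33 times as many. Window by window, stages 4 and 5 were not the closest pair. Their correlation over windows was 0.932 in CHG and 0.856 in CHH, against 0.957 and 0.875 for stages 1 and 2. Stage 4 also had the most windows at exactly 0, 41.0% in CHG and 27.8% in CHH. Noise in stage 4 may thus raise the counts it is compared by, which was not tested because depth is unknown. Another pair of fruit stages, 1 and 2, had 183682 CHH windows higher, more than leaf and stage 1. That pair had 23007 CHG and 9208 CHH windows lower, fewer than leaf and stage 1. The raised background of stage 2 can add higher calls and remove lower ones. In unmethylated windows CHH was 2.49% in stage 2 and 0.516% in stage 1. From stage 3 to stage 4, 56587 CHG and 63555 CHH windows were lower, more than from leaf to stage 1. From stage 1 to stage 5 they numbered 57815 and 24315, again more. How the lower windows compare thus depends on the fruit pair chosen. Fewer were lower only between stages 1 and 2.

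Windows with higher CHG in stage 1 formed 56989 regions, against 57834.1 (57679 to 57990) with the calls placed at random among windows of like level. With calls this dense, grouping can also merge regions, so their number alone does not show whether calls are grouped. Of these regions, 14888 held at least 4 windows, against 11130.2 (10995 to 11312), so larger regions were more frequent than in the random placements. The region with the most CHG calls, on Ro01 from 7325001 to 7328950, held 32 called windows, and its CHG level was 11.3% ± 12.9 in leaf and 65.6% ± 16.1 in stage 1. CHH in that region was 1.42% in leaf and 35.4% in stage 1, whereas CG was 88.2% and 92.4%. On Ro05 from 29132101 to 29134950, all 26 complete windows were called, with CHG at 16.0% ± 16.6 in leaf and 80.0% ± 6.84 in stage 1. The other 2 regions were on Ro05 from 34842451 to 34846250, where CHG was 25.6% ± 19.5 and 58.1% ± 23.6, and on Ro04 from 11747101 to 11749300, where it was 10.4% ± 10.3 and 48.3% ± 23.7. For CHH the first region, on Ro04 from 15416451 to 15422200, had all 66 complete windows called, and CHH was 7.03% ± 3.45 in leaf and 39.7% ± 8.74 in stage 1. It was followed by Ro07 from 30071951 to 30075600, with CHH of 11.7% ± 7.12 and 38.4% ± 10.6, and Ro07 from 23270551 to 23273400, with 22.4% ± 7.97 and 64.1% ± 8.61. On Ro01 from 27591701 to 27595000, CHH was 14.1% ± 6.005 in leaf and 37.9% ± 8.83 in stage 1. In these 4 CHH regions CG was at least 90.4% in both data sets.

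Regions with more CG methylation in stage 1 were shorter. On Ro05 from 7165351 to 7165950, CG was 0.599% ± 1.14 in leaf and 53.9% ± 12.4 in stage 1, CHG was 0.154% and 70.3%, and CHH was 0.745% and 57.4%. CG was 37.4% ± 18.2 in leaf and 72.1% ± 22.0 in stage 1 on Ro03 from 6277251 to 6278650. It was 14.8% ± 14.7 and 71.5% ± 19.7 on Ro05 from 17163251 to 17164050, and 43.6% ± 18.5 and 95.3% ± 4.96 on Ro04 from 5459951 to 5461100. In the 4 regions with lower CG in stage 1, CG was lower still in stage 5. On Ro02 from 3794201 to 3794900 it was 87.8% ± 8.71 in leaf, 35.3% ± 9.95 in stage 1 and 6.47% in stage 5. On Ro05 from 3265001 to 3265600 it was 79.8% ± 18.7 in leaf, 16.0% ± 10.4 in stage 1 and 1.59% in stage 5. On Ro04 from 10738451 to 10738850 it was 76.2% ± 10.3, 12.7% ± 12.8 and 4.10%, and on Ro02 from 39843101 to 39843650 it was 83.7% ± 6.80, 33.9% ± 13.9 and 9.54%, in the same order.

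Regions lower in stage 1 in CHG or CHH had at most 7 called windows. CHG was 82.3% ± 26.9 in leaf and 38.3% ± 27.3 in stage 1 on Ro02 from 19064701 to 19065600, and 60.9% ± 30.3 and 36.4% ± 27.2 on Ro07 from 17246701 to 17247750. In the latter only 7 of 13 complete windows were called, and the difference was -24.5 points over all of them and -48.1 over the called ones. The Ro05 region with CG loss appeared again, from 3265051 to 3265600, with CHG of 81.8% ± 11.5 and 9.79% ± 9.05. On Ro02 from 19596951 to 19597650, CHG was 78.5% ± 25.8 and 28.6% ± 28.8. CHH was 29.8% ± 11.4 in leaf and 12.7% ± 9.56 in stage 1 on Ro01 from 26232601 to 26233300, and 43.9% ± 20.2 and 5.96% ± 6.002 on Ro02 from 26396751 to 26397250. It was 30.6% ± 23.4 and 6.56% ± 12.6 on Ro02 from 21371001 to 21371400, and 32.6% ± 14.6 and 12.3% ± 6.46 on Ro01 from 32671701 to 32672050.

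Bins with more CG had larger CHG and CHH differences in points between leaf and stage 1, but also more CHG and CHH to begin with. CHG was higher in stage 1 in 2887 of 2910 bins of 100 kb and CHH in 2885. Over 4 equal groups of bins ordered from lowest to highest CG, the CHG difference was 2.10, 5.75, 10.1 and 12.7 points, and the CHH difference was 0.943, 2.35, 3.97 and 4.99 points. Relative to leaf, CHG in stage 1 was 1.29, 1.36, 1.36 and 1.32 times as high, which is nearly even, and CHH was 1.41, 1.69, 1.81 and 1.73 times as high. The CG difference changed sign along the same order, at -0.355, 0.412, 1.49 and 2.27 points. These values were not corrected for background, and unmethylated windows read 0.930% CG in leaf and 0.576% in stage 1. The negative value in the lowest group may thus come largely from background. Of the 26973 windows with higher CG, 12394 also had higher CHG, against 5414.04 for independent calls among windows of like level, and 650 had lower CHG, against 649.653. For CHG and CHH, 45541 windows were higher in both, against 26858.8, while 2496 had lower CHG and higher CHH, against 3345.76, and 1790 the reverse, against 2614.72.

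Leaf was also compared with each later stage. CHG remained above leaf by 8.88 points in stage 2 (SD 0.264), 5.84 in stage 3 (SD 0.214), 4.89 in stage 4 (SD 0.186) and 4.42 in stage 5 (SD 0.174). CHH was above leaf by 7.87 points in stage 2 (SD 0.265), where the background was raised, and by 4.51 (SD 0.224), 3.66 (SD 0.204) and 3.90 points (SD 0.210) in stages 3, 4 and 5. CG was 0.852 points above leaf in stage 2 (SD 0.151), or 0.193 points after correction for the background, and the CHG difference in stage 2 became 7.82 points. CG lay below leaf from stage 3 on, with differences of -0.644 (SD 0.176), -0.827 (SD 0.188) and -1.30 points (SD 0.198). With all windows as deposited, in which values appear displaced, CG was 16.0 and 15.04 points above leaf in stages 4 and 5. CHH was then below leaf in stages 3 to 5, at -8.64, -7.97 and -9.23 points. Windows with CG lower than leaf rose in number from 34646 in stage 2 to 58199, 69428 and 75975 in stages 3, 4 and 5, while those with higher CG numbered 25743, 24638, 24629 and 22348. The number of CHG windows higher than leaf was 253435 in stage 2, 199065 in stage 3, 184502 in stage 4 and 153173 in stage 5.

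The first CG region lower than leaf was on Ro07 from 40775951 to 40777050 in stage 2, where CG was 84.0% ± 12.6 in leaf and 43.5% ± 12.8 in stage 2. In stages 3, 4 and 5 it was a region of Ro06 between 26917551 and 26922000, where CG was 85.1% ± 13.9 in leaf, 34.2% ± 11.98 in stage 3 and 20.8% ± 9.27 in stage 5 from 26917751 on, and 25.6% ± 11.1 in stage 4 over the slightly longer region called there. The first CG region higher than leaf was on Ro02 from 31263801 to 31264450 in stage 2, with CG of 26.4% ± 6.90 in leaf and 70.4% ± 13.2 in stage 2. In stages 3 to 5 it was on Ro04 from 8823751, ending at 8824800 in stage 3 and at 8824900 in stages 4 and 5. CG there was 5.55% ± 11.99 in leaf and 55.2% ± 19.1 in stage 3, and 5.18% ± 11.6 in leaf against 51.0% ± 19.9 in stage 4 and 52.0% ± 19.99 in stage 5.

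**Figure D3:**
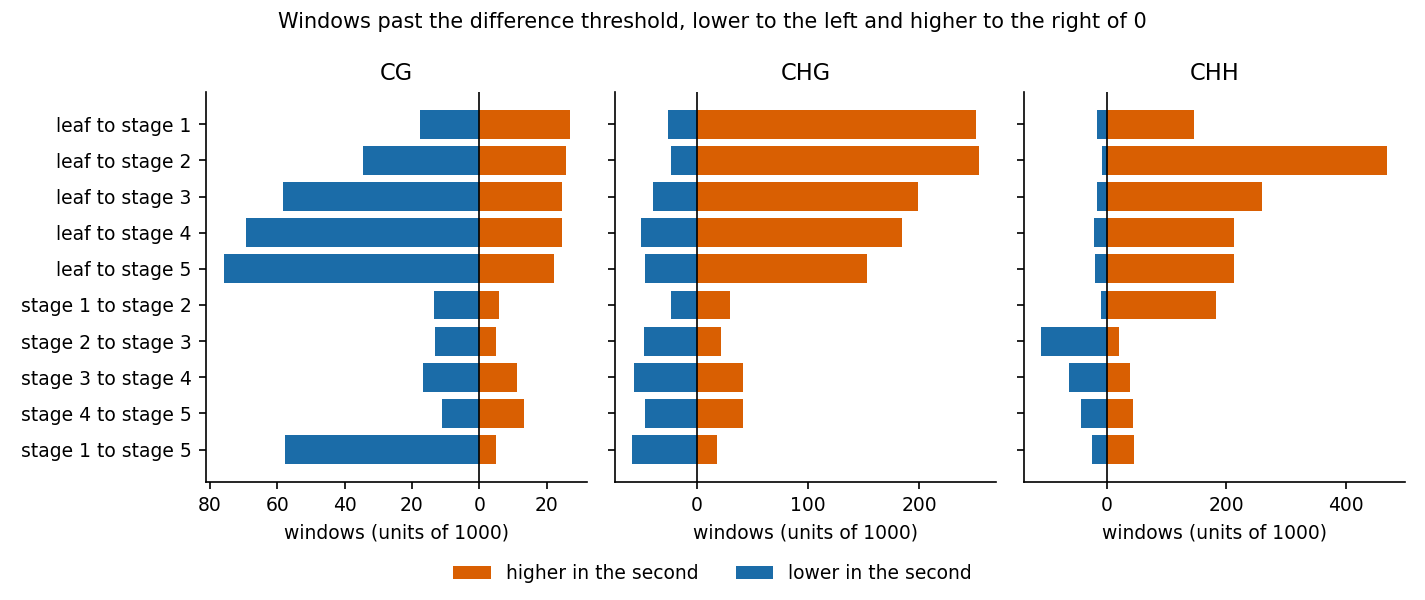
Windows past the difference threshold (horizontal axis, in units of 1000) in the 10 comparisons, with bars to the right for windows higher and to the left for windows lower in the second data set, and a separate scale for each context. CG windows lower than leaf increase from 17699 in stage 1 to 75975 in stage 5, and CHH windows higher than leaf are most numerous in stage 2 (469775), whose background is raised.

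Successive fruit stages showed a rise of CHH into stage 2 and lower levels after it, except for CHH from stage 4 to stage 5. From stage 1 to stage 2, CHH was 4.84 points higher (SD 0.108) and CHG 1.32 points higher (SD 0.0602), beside a background rise from 0.516% to 2.49% in unmethylated windows. Corrected for that background, the CHH rise was 3.09 points and the CHG rise 0.0383 points, so that little of the latter remained. CG differed by -0.0750 points (SD 0.0552), with 6 of 7 chromosomes in that direction, and by -0.905 points after the correction. From stage 2 to stage 3, CHH fell by 3.36 points (SD 0.0433), CHG fell by 3.03 (SD 0.0577) and CG fell by 1.497 (SD 0.0311), as the background returned to 0.561%. With the correction, CHH fell by 1.64 points, CHG fell by 1.77 and CG fell by 0.670. From stage 3 to stage 4 the differences were -0.850 points in CHH (SD 0.0206), -0.952 in CHG (SD 0.0552) and -0.183 in CG (SD 0.0309). From stage 4 to stage 5 they were 0.248 in CHH (SD 0.0157), -0.470 in CHG (SD 0.0359) and -0.471 in CG (SD 0.0187). The CHH difference between stages 4 and 5 became -0.0983 points with CHH values moved back and -0.00209 points with the background removed, so its direction depended on the processing.

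The windows called between successive stages were most one-sided for CHH into and out of stage 2. From stage 1 to stage 2, 183682 CHH windows were higher and 9208 lower, and from stage 2 to stage 3, 20666 were higher and 109781 lower. CHH windows numbered 38605 higher and 63555 lower from stage 3 to stage 4. CG windows lower numbered 13302, 13286, 16650 and 11069 in the 4 steps, and those higher numbered 5914, 5120, 11142 and 13310. Between stages 4 and 5 the more frequent direction depended on the threshold: CG windows numbered 29717 higher and 33802 lower at 20 points, and CHH windows 12381 higher and 13755 lower at 25 points. The first CHH region higher in stage 2 was on Ro06 from 46554101 to 46558150, at 31.9% ± 9.22 in stage 1 and 48.8% ± 9.43 in stage 2. The first lower there was on Ro01 from 29914601 to 29915100, at 31.98% ± 20.8 and 16.0% ± 17.0. From stage 2 to stage 3, CHH was 34.7% ± 11.7 and 15.6% ± 12.8 on Ro01 from 17748401 to 17750150, and 10.4% ± 8.42 and 26.3% ± 15.7 on Ro06 from 20330201 to 20330900. From stage 3 to stage 4 it was 12.4% ± 10.7 and 35.3% ± 8.99 on Ro06 from 23515301 to 23516100, and 35.8% ± 12.1 and 13.5% ± 9.65 on Ro05 from 23400151 to 23401250. From stage 4 to stage 5 it was 5.92% ± 6.501 and 24.7% ± 14.3 on Ro05 from 22476401 to 22477200, and 53.4% ± 26.3 and 28.6% ± 15.9 on Ro05 from 33761801 to 33762700. Not all of these changes lasted: in stage 5, CHH was 32.2% on Ro05 from 23400151 and 20.4% on Ro06 from 23515301. On Ro01 from 17748401 it stayed lower, at 17.4% in stage 4 and 19.7% in stage 5.

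Regions first in CG between successive stages had at most 12 called windows. CG was 89.1% ± 7.502 in stage 1 and 44.6% ± 8.89 in stage 2 on Ro03 from 21858801 to 21859600, and 23.7% ± 12.7 and 66.7% ± 8.62 on Ro06 from 24138801 to 24139150. From stage 2 to stage 3 it was 79.1% ± 6.98 and 18.3% ± 12.9 on Ro07 from 32144351 to 32144800, and 52.4% ± 9.58 and 100% on Ro05 from 23570401 to 23570750. From stage 3 to stage 4 it was 88.8% ± 11.1 and 35.8% ± 24.5 on Ro05 from 23304501 to 23305100, and 42.3% ± 18.6 and 98.6% ± 3.78 on Ro04 from 5460351 to 5460750. From stage 4 to stage 5 it was 81.5% ± 26.2 and 27.6% ± 20.4 on Ro01 from 33205451 to 33206400, and 4.57% ± 10.2 and 53.5% ± 27.4 on Ro03 from 17113101 to 17113650. Several of these changes did not last. CG was 30.8% in stage 3 on Ro06, 30% in stage 4 on Ro05 from 23570401 and 70.3% in stage 5 on Ro05 from 23304501. In stage 1 it was 96.3% on Ro04, 53.5% on Ro01 and 56.8% on Ro03 from 17113101. It stayed lower on Ro03 from 21858801 and on Ro07, at 31.4% and 28.4% in stage 5. With 1 data set per stage, noise in a single data set cannot be told from change.

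The comparison of stage 1 with stage 5 addresses ripening as a whole. CG and CHG methylation were lower at the last stage and CHH was higher: CG fell by 2.23 points (SD 0.106), CHG fell by 3.14 (SD 0.114) and CHH was 0.879 points higher (SD 0.0565), each on 7 of 7 chromosomes. With CHH values moved back the CHH difference was 0.469 points, with 93125 windows higher and 74248 lower. CG losses prevailed, with 57793 windows lower and 4881 higher, so that 92.2% of CG calls were losses. In CHG, 57815 windows were lower and 18733 higher. In CHH, 45133 were higher and 24315 lower. CG losses between successive stages numbered 11069 to 16650. CHG losses between successive stages numbered 23007 to 56587, close to the 57815 at their highest, and CHH gains numbered 20666 to 183682. With all windows as deposited, the CG difference was 21.8 points and the CHH difference -1.43 points, opposite in sign to those of complete windows.

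CG losses formed 12254 regions, against 6939.9 with the calls placed at random among windows of like level, and 2659 of them held at least 4 called windows, against 347.9. With calls placed among all complete windows, CG losses from stage 4 to stage 5 also exceeded their random number, at 1057 regions against 123.6. From stage 1 to stage 5 that random number was 3123.6. An excess of regions is thus not particular to stage 1 to stage 5, and noise shared by neighbouring windows was not excluded. The first region of CG loss from stage 1 to stage 5, on Ro06 from 26917751 to 26922000, had 39 of its 42 complete windows called. Its CG level was 85.1% in leaf, 70.1% ± 12.8 in stage 1, 58.8% in stage 2, 34.2% in stage 3, 24.6% in stage 4 and 20.8% ± 9.27 in stage 5. CHG in it was 54.2% in stage 1 and 18.4% in stage 5. The loss was not confined to the region: the 29 complete windows within 3000 bp to its left had CG of 84.4% ± 19.5 in stage 1 and 58.7% ± 31.7 in stage 5. The 20 to its right were unmethylated, at 0.206% ± 0.649 and 0.449% ± 0.764. In the next 2 regions methylation lay almost entirely in CG. On Ro07 from 40775951 to 40777750, CG was 83.8% ± 17.3 in stage 1 and 25.4% ± 17.8 in stage 5, with CHG at 0.771% and 0.674%. On Ro01 from 9148151 to 9149850, CG was 77.1% ± 23.3 and 35.0% ± 19.3, with CHG at 0.538% and 0.586%. On Ro03 from 39564401 to 39566450, CG was 66.7% ± 17.7 in stage 1 and 27.1% ± 18.9 in stage 5.

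**Figure D4:**
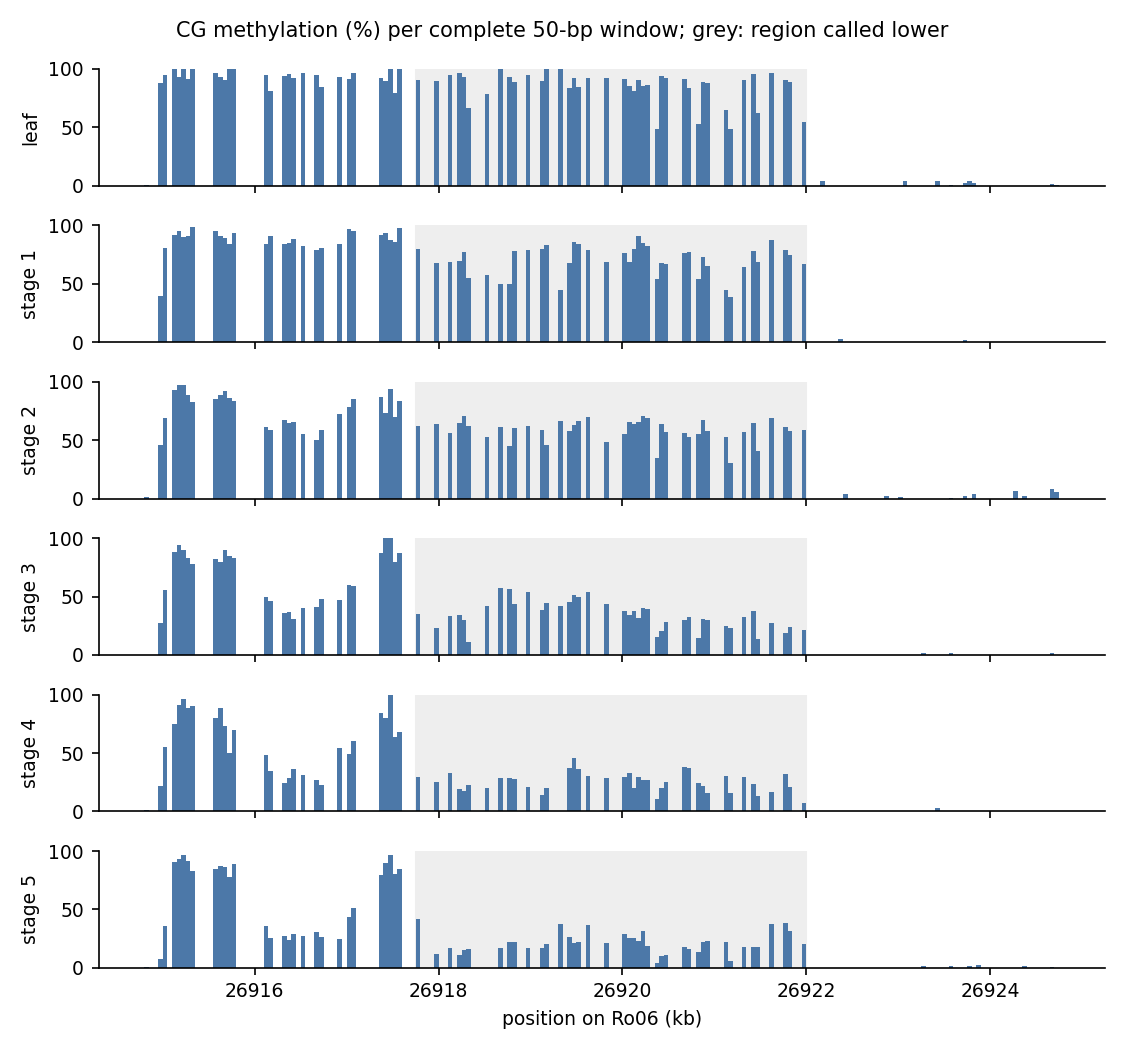
CG methylation (percent, vertical axis) of each complete 50-bp window on Ro06 (horizontal axis, kb) in the 6 data sets, with the region from 26917751 to 26922000 in grey. Gaps are windows without all 18 values, and the mean in the grey region goes from 85.1% in leaf through 70.1% in stage 1 to 20.8% in stage 5.

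CHG and CG were both lost in 11560 windows, against 4185.9 for independent calls among windows of like level. Joint gain of CG and CHG was further above that expectation, in 894 windows against 70.3139. Opposite calls with higher CG and lower CHG also exceeded that expectation, at 554 against 311.424, while those with lower CG and higher CHG did not, at 472 against 523.494. Lower CHH exceeded it beside higher CG, at 332 against 138.569, and beside higher CHG, at 703 against 433.625. Higher CHH exceeded it beside lower CHG, at 2528 against 2059.15, but not beside lower CG, at 809 against 1037.22. An excess is thus not particular to joint loss. CHG losses formed 9216 regions, against 5600.2 with the calls placed at random among windows of like level. Of these regions, 790 held at least 4 called windows, against 78. With calls placed among all complete windows, the random number of regions was 3146. CHG losses from stage 4 to stage 5 formed 7017 regions, against 2078.4 placed in that way, so this excess is not particular to stage 1 to stage 5 either. On Ro05 from 32708001 to 32708950, CHG was 61.6% ± 15.2 in stage 1 and 12.8% ± 6.52 in stage 5, and CG was 73.8% and 16.7%. On Ro04 from 31145601 to 31146700, CHG was 73.4% ± 10.5 and 30.3% ± 9.53, and CG was 89.9% and 35.7%. The Ro06 region of CG loss also appeared here, from 26919451 to 26920850, with CHG at 58.7% ± 17.4 and 16.9% ± 5.74. On Ro07 from 772101 to 773000, CHG was 67.4% ± 21.6 and 28.5% ± 13.1. Of the 1924 regions with CHG gain, 42 held at least 4 called windows, and the 4 named here held 5 each, the most of any. CHG was 33.5% ± 24.9 and 81.9% ± 19.8 on Ro07 from 22067751 to 22068400, 31.5% ± 34.6 and 79.2% ± 33.2 on Ro01 from 26125101 to 26125500, 46.9% ± 14.7 and 87.8% ± 17.3 on Ro06 from 39052501 to 39052800, and 31.9% ± 22.7 and 70.2% ± 25.4 on Ro01 from 31422451 to 31422850.

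CHH gains between stages 1 and 5 lay in regions with high CG. On Ro06 from 11708451 to 11710300, CHH was 31.0% ± 7.56 in stage 1 and 45.7% ± 8.13 in stage 5, and CG was 94.7% and 96.5%. Of its 33 complete windows 17 were called, and its difference of 14.8 points over all of them was below the 15 points required of a window, against 18.9 over the called ones. CHH was 14.8% ± 5.08 and 40.1% ± 11.9 on Ro06 from 39904651 to 39905400, 13.8% ± 7.66 and 30.4% ± 17.9 on Ro01 from 20267051 to 20268600 (16.6 points over all windows and 27.4 over called ones), and 28.1% ± 11.05 and 47.3% ± 12.8 on Ro06 from 16053801 to 16054700. CHH losses were seen on Ro02 from 24434951 to 24435850, with 39.1% ± 23.0 and 12.1% ± 15.7, and on Ro06 from 24412751 to 24413300, with 47.1% ± 18.3 and 17.6% ± 15.8. CHH was 30.8% ± 23.3 and 6.74% ± 9.27 on Ro07 from 34479051 to 34479850, and 34.5% ± 21.4 and 10.5% ± 9.59 on Ro01 from 29914601 to 29915150. The few CG gains held at most 6 called windows. CG was 31.2% ± 20.3 and 89.1% ± 12.2 on Ro05 from 18912501 to 18912850, and 16.7% ± 25.8 and 69.0% ± 34.2 on Ro06 from 10191201 to 10191650. It was listed at 0 in stage 1 and was 44.2% ± 12.3 in stage 5 on Ro03 from 17103951 to 17104250, and it was 54.4% ± 12.2 and 97.3% ± 4.14 on Ro07 from 30321301 to 30321600.

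Along the genome, CG was lower in stage 5 than in stage 1 in 2896 of 2910 bins and CHG in 2900, while CHH was higher in 2767. The share of windows with CG loss was 2.62%, 3.09%, 2.36% and 1.24% over the 4 groups of bins ordered from lowest to highest CG. Relative to stage 1, mean CG in stage 5 was 0.908, 0.937, 0.963 and 0.985 times as high in that order. The relative decline in mean CG was thus largest in the bins with least CG. CHG losses made up 0.944%, 1.78%, 2.39% and 4.37% of windows in that order, and CHG gains rose as well, at 0.1797%, 0.458%, 0.717% and 1.73%. Relative to stage 1, CHG in stage 5 was nearly even over the groups, at 0.882, 0.8897, 0.896 and 0.9004 times. The stage 1 level of CHG rose in the same order, from 9.40% to 53.0%. Whether that level accounts for the trend in CHG calls was not tested. CHH gains made up 0.483%, 1.22%, 1.92% and 3.81% of windows and CHH losses 0.597%, 0.885%, 0.974% and 1.51%, with losses the more frequent in the lowest group. CHH in stage 5 was 1.07, 1.09, 1.11 and 1.16 times that in stage 1. The bins were not corrected for background, which for CHH was 0.516% in stage 1 and 0.695% in stage 5. In the lowest group the CHH difference was only 0.222 points, so much of it may be background.

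Followed through all 6 data sets, windows with CG loss between stages 1 and 5 had mean CG of 79.2% in leaf and of 75.8%, 59.1%, 48.9%, 45.04% and 33.3% in stages 1 to 5. Stages 1 and 5 were used to choose these windows and the stages between them were not. In 46.0% of them, stages 2, 3 and 4 lay in descending order, against 25.9% expected from uncalled windows of equal level over these stages. Windows with CHG loss had mean CHG of 43.5% in leaf and of 71.4%, 55.8%, 49.9%, 47.0% and 28.6% in stages 1 to 5, with 25.8% in descending order, against 29.0% in uncalled windows of equal level. Windows with CHH gain had mean CHH of 9.82% in leaf and of 13.5%, 29.6%, 24.2%, 22.5% and 36.1%. Their fall of 7.07 points from stage 2 to stage 4 was close to the 6.95 points in windows of equal level, and 6.77% had these stages in ascending order, against 3.93% in uncalled windows of equal level.

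**Figure D5:**
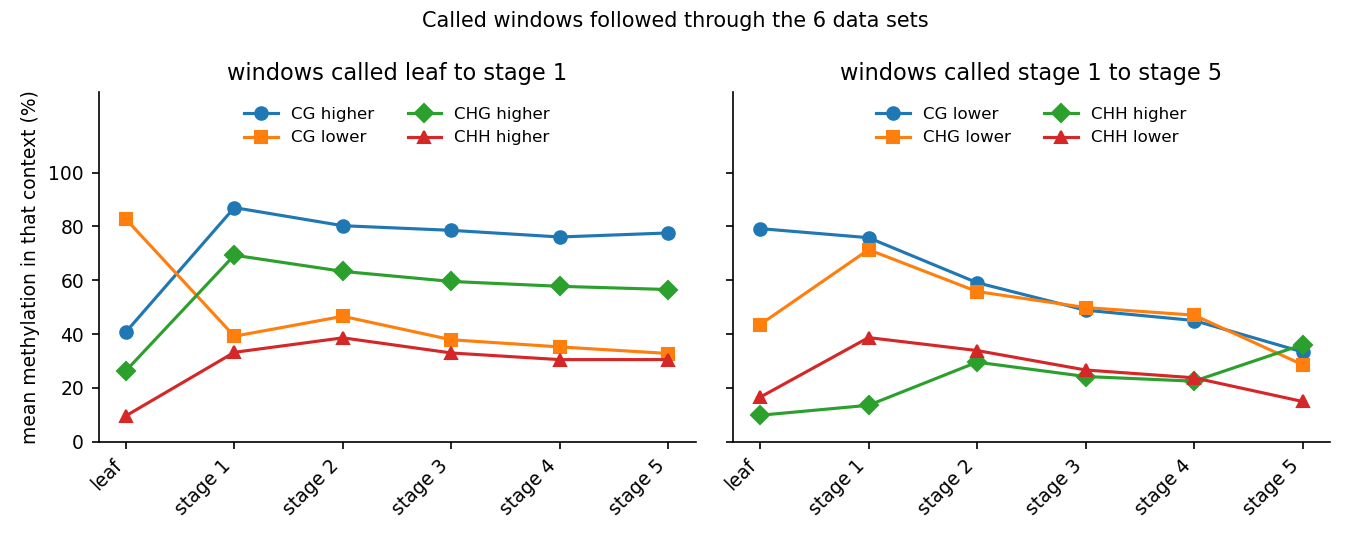
Mean methylation (percent, vertical axis) in the 6 data sets of windows called from leaf to stage 1 (left) and from stage 1 to stage 5 (right), each line in the context in which the windows were called. Windows with CG loss from stage 1 to stage 5 pass through 59.1%, 48.9% and 45.04% in stages 2, 3 and 4.

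Part of the windows that differed between leaf and stage 1 also differed between leaf and stage 5. Of the 250558 windows with CHG higher in stage 1, 116996 (46.7%) were also called higher in stage 5 than in leaf. In CHH, 99447 of 146763 (67.8%) were called in both. In CG, 16989 of the 26973 higher windows (63.0%) and 13207 of the 17699 lower windows (74.6%) were called in both. Both comparisons use the same leaf data set, and in simulated data without effects the share called in both was 33.3% for CHG, 28.5% for CHH, 44.0% for CG higher and 18.7% for CG lower. That simulation called only 41109, 42612, 8591 and 8557 windows in stage 1, so its calls are not like the real ones and its shares are no close expectation. No second leaf data set was analysed here, and how much of the overlap comes from the shared leaf values is not known.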

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

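The tests of the moved values, of the choice of windows, of CG in unmethylated windows, of overall signal loss in leaf and of plastid DNA in windows chosen on stages 2 to 5 were chosen after the results were seen; those of conversion over all windows and of plastid DNA in windows with lower CHG in leaf were written beforehand. Windows with 12 of 18 values, which the comparisons leave out, had a mean of 33.8% in the column named leaf CHH, against 4.33% in complete windows. That column correlated less with the stage 1 to 3 columns named CHH (0.731) than with the column named stage 1 CHG (0.967), which argues against true CHH methylation. Columns at odd positions correlated at 0.943, in line with dropped cells and values moved left. Authors' processing is the candidate cause, and no biological explanation other than true CHH methylation was tested.

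CHH was highest in stage 2, at 12.2%. Incomplete conversion would raise unmethylated windows as well, and there the CHH excess of stage 2 over the other fruit stages was 1.94 points, 47.3% of the 4.10 points over all complete windows (45.7% to 48.2% by chromosome). The bound set beforehand was 50%, so incomplete conversion is argued against as the whole cause, by a small margin and assuming that it acts alike in all windows. For the rise in unmethylated windows it stays open and may be the cause, since CG there rose by 91.3% of the CHH rise, as a failure that ignores context would give. The choice of windows is argued against, since stage 2 was highest on 7 of 7 chromosomes in windows with 6 values too; with the background removed, stage 2 was at 9.96% and stage 3, the next, at 8.32%, and a true difference between ripening stages stays open, untested for lack of replicates.

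CHG was lower in leaf than in all 5 fruit stages. A loss of signal in all contexts is argued against, since the leaf to stage 1 ratio of CG (0.983) exceeded that of CHG (0.748) by 0.235. Unmethylated plastid DNA read as nuclear is argued against as the whole cause as well: in 985184 windows chosen on stages 2 to 5 and above 0 in stage 1, the median ratio was 0.989 for CG and 0.758 for CHG, a gap of 0.231 (0.216 to 0.2398 by chromosome). In windows chosen for lower CHG in leaf the gap was 0.591, which the choice itself widens. A difference between the tissues may underlie the pattern, as a hypothesis, and a difference between libraries that acts on CHG and CHH alone cannot be excluded with 1 data set per tissue.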

How the results depend on the processing

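All windows as deposited, CHH moved back, all contexts corrected for background and levels over called windows alone were chosen after seeing the data, and the other alternatives were planned. No paired analysis was possible because each group had 1 data set and the columns carry no replicate numbers, and leaving out a replicate was impossible for the same reason. Not run, because the files hold no calls, were weighting by calls, coverage minimums of 10, 20 and 40, leaving out the 1% of windows with most calls, a stricter adjusted p and thinning; not run without an annotation were the alternatives for features and gene lists. The unknown depth limits single windows most. A merge distance of 500 bp kept all 60 counts of regions within 1.5 times, and all 96 named regions moved by less than their SD over called windows alone. Lists below follow the order leaf to stages 1 to 5, stages 1 to 2, 2 to 3, 3 to 4, 4 to 5 and 1 to 5.

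With all windows as deposited, 15 of 30 level differences changed sign and 15 moved by more than the SD between chromosomes. CG differences were -6.79, 8.34, -3.54, 16.0, 15.04, 15.1, -11.9, 19.6, -1.004 and 21.8 points. CHG differences were 14.4, 7.64, 15.7, 13.9, 12.6, -6.78, 8.09, -1.82, -1.29 and -1.80 points. CHH differences were -7.79, 3.96, -8.64, -7.97, -9.23, 11.8, -12.6, 0.665, -1.25 and -1.43 points. Values under other contexts and data sets are the candidate cause. With CHH moved back, the differences were 2.87, 7.13, 4.18, 3.43, 3.34, 4.26, -2.95, -0.745, -0.0983 and 0.469 points. With CHH corrected for background they were 3.23, 6.32, 4.68, 3.95, 3.95, 3.09, -1.64, -0.727, -0.00209 and 0.718 points. From stage 4 to stage 5 the sign thus turned under both alternatives for CHH, and the cause was not tested. Of the other CHH differences all kept their sign under both. With CG and CHG corrected for background, CG differences were 1.099, 0.193, -0.477, -0.626, -1.203, -0.905, -0.670, -0.149, -0.577 and -2.30 points, and CHG differences were 7.78, 7.82, 6.05, 5.15, 4.52, 0.0383, -1.77, -0.899, -0.637 and -3.26 points. All 20 kept their sign, and the raised stage 2 background is what this correction removes. CHH moved back gave 320047, 922629, 533431, 444516, 443946, 362701, 63560, 90848, 90488 and 93125 windows higher and 47867, 39664, 46274, 52493, 66819, 42025, 222383, 134401, 110696 and 74248 lower, among 5381933 windows.

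With lower thresholds of 20 points (10 for CHH) more windows pass by construction. CG windows higher numbered 62439, 59070, 54247, 53662, 48710, 16334, 14313, 29217, 29717 and 11862. CG windows lower numbered 38892, 68431, 101839, 115153, 122117, 41957, 42889, 41779, 33802 and 110642. CHG windows higher numbered 471165, 491988, 390501, 357205, 318966, 77757, 48074, 86013, 86109 and 40184. CHG windows lower numbered 47923, 42808, 70378, 87847, 84581, 58901, 122162, 122449, 102955 and 151384. CHH windows higher numbered 301493, 773033, 468596, 388834, 403810, 413674, 40623, 76919, 95405 and 107918. CHH windows lower numbered 30548, 13733, 27392, 35563, 31813, 18728, 264674, 138307, 88916 and 51834. The share of the stage 1 to 5 difference present at stage 3 was then 62.5% for CG loss against 63.4%, 50.3% for CHG loss, and 56.1% for CHH gain against 47.4%. Because windows were chosen on stages 1 and 5, an unchanged stage 3 would also fall between them, so the share does not measure gradual change; the cause of the move was not tested.

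With higher thresholds of 50 points (25 for CHH) fewer windows pass by construction. CG windows higher numbered 9063, 8811, 9125, 9295, 8329, 1787, 1601, 3662, 5058 and 1620. CG windows lower numbered 4765, 8882, 21582, 28300, 32973, 1940, 3269, 5719, 3100 and 12418. CHG windows higher numbered 55796, 54622, 49286, 50380, 37032, 8181, 7463, 15494, 14967 and 6535. CHG windows lower numbered 9453, 8027, 14979, 20421, 17086, 6554, 13103, 19875, 15730 and 13843. CHH windows higher numbered 45565, 160650, 90857, 76829, 68163, 35966, 7124, 13261, 12381 and 10993. CHH windows lower numbered 6448, 3492, 6661, 8512, 8285, 2867, 24672, 18011, 13755 and 7370.

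With at least 4 called windows per region, fewer regions pass by construction. CG regions higher numbered 470, 459, 324, 344, 267, 23, 16, 46, 62 and 10. CG regions lower numbered 175, 907, 2208, 2798, 3845, 146, 109, 100, 41 and 2659. CHG regions higher numbered 14888, 15211, 9646, 8148, 5772, 125, 77, 399, 392 and 42. CHG regions lower numbered 108, 94, 354, 607, 551, 105, 463, 702, 466 and 790. CHH regions higher numbered 8169, 39806, 19240, 14485, 14903, 10519, 204, 652, 898 and 906. CHH regions lower numbered 81, 35, 78, 134, 115, 27, 3948, 1459, 723 and 255. A merge distance of 50 bp kept 50 of 60 counts of regions within 1.5 times. The others, all in CHG, were 1672 lower from leaf to stage 2, 2170 higher and 1606 lower from stage 1 to 2, 1501 higher and 4506 lower from stage 2 to 3, 3949 higher and 5915 lower from stage 3 to 4, 4055 higher and 4568 lower from stage 4 to 5, and 1215 higher from stage 1 to 5.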

Other observations

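Complete windows were also sorted by their mean over the 6 data sets, a grouping chosen after the data were seen. In 193211 windows methylated in CG alone (CG at least 50%, CHG under 10%, CHH under 5%), CG was 88.4% in leaf, 89.7% in stage 1, 86.9% in stage 2, 86.2% in stage 3, 86.1% in stage 4 and 85.2% in stage 5, with SDs between chromosomes of 0.226 to 0.357. Of these windows, 3.23% lost CG between stages 1 and 5 and 0.0543% gained it. They held 10.8% of all windows with CG loss, so the loss was not particular to them. Over all complete windows the share with CG loss was 2.34%, but these include the unmethylated windows. There the bound of 5% on mean CG leaves no room for a loss of 30 points, so none could be called. In 969389 windows methylated in CG and CHG (at least 50% and 30%), CHG was 52.2% ± 0.520 in leaf and 69.0% ± 0.158, 69.5% ± 0.189, 65.7% ± 0.191, 64.0% ± 0.181 and 62.6% ± 0.192 in stages 1 to 5, while CG stayed between 91.3% and 93.7%.

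In 291948 windows with mean CHH of at least 20%, CHH was 15.9% ± 0.236 in leaf and 27.9% ± 0.439, 38.7% ± 0.591, 32.96% ± 0.481, 30.9% ± 0.425 and 30.4% ± 0.373 in stages 1 to 5. Of these windows, 3.08% lost CG between stages 1 and 5, a share close to that in windows methylated in CG alone. In the windows methylated in CG and CHG it was 1.86%.

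A hypothesis formed from these data is that CG loss proceeds gradually from stage 1 to stage 5, against the alternative that calls are random scatter of single windows. The test on pairs of windows was written beforehand, and those on the course through the stages and on shuffled directions were chosen after the values were seen. Pairs of called windows 1000 bp apart had the same direction more often than the split of calls gives by 9.69 points in CG, by -1.53 points in CHG and by 6.37 points in CHH, against a bound of 10 points, so this test alone excluded scatter in no context. Against the split within these pairs, the excess was 2.12 points in CG, 1.085 in CHG and 3.34 in CHH. From stage 2 to stage 4, on which windows were not chosen, CG in windows with CG loss declined by 14.1 points, which is 7.39 points (SD 0.418 between chromosomes) more than in windows of equal level. For CHG loss the excess was 1.98 points (SD 0.358), and for CHH gain it was -0.116 points (SD 0.245).

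With the places of all calls kept and their directions shuffled 100 times among calls of like level, CHH gains formed at most 7644 regions, against 8255 observed, with 7 of 7 chromosomes above their highest shuffle. The share of pairs 1000 bp apart with the same direction was 60.9% in CHH, against at most 58.3%. CG losses formed 12254 regions, against at most 12082, with 6 of 7 chromosomes above. CHG losses formed 9216 regions, against at most 9067, but on only 2 of 7 chromosomes. Regions of at least 4 called windows numbered 906 for CHH gains, against at most 661 in the shuffles. They numbered 2659 for CG losses, against at most 2467, and 790 for CHG losses, against at most 669. For CHH gains, the shuffles argue against scatter of single windows as the whole cause, although the pairs stayed under their bound. Their mean change from stage 2 to stage 4 showed no excess either. Stages 2 to 4 lay in ascending order in 6.77% of these windows, against 3.93% in uncalled windows of equal level. For CG losses the course argues against it, although the pairs stayed under their bound and 1 chromosome did not exceed its highest shuffle. For CHG losses scatter and change cannot be told apart, because the values go both ways. The mean decline and the regions of at least 4 called windows were in excess. Stages 2 to 4, however, lay in descending order in 25.8% of windows, against 29.0% in uncalled windows of equal level. The pairs and 5 chromosomes in the shuffles showed no excess beyond their bounds. Neighbouring windows can share reads, so noise common to them was not excluded. Gradual loss may thus hold for part of the CG calls, and a likeness between libraries made together could give the same course, which no label allows to be tested.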
